A study of Homo sapiens with 8 samples.

How the data were processed

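Total RNA of resting and activated human B cells had been extracted with TRIzol and labelled as biotinylated cRNA for Affymetrix arrays, per the labels' protocols. The authors deposited 1 table of log2 values, 1 column per array, and per the submitters' processing notes the values were made with RMA, which corrects background, normalizes arrays by quantiles and summarizes the probes of a probe set. The version of RMA, the chip definition and the genome build were not given in the sources used here, nor whether all 8 arrays were normalized together. The log2 scale was read from the deposited values, which ran from 2.72 to 14.5. Quantile normalization assumes that arrays share 1 distribution of signals, so a shift of most genes in 1 direction cannot be measured reliably, and RMA compresses differences at low signal. The number of arrays, not a read depth, sets the precision. No scanner files or detection calls were used here, so no probe set was called absent.

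The table had 1259 probe sets, 0 missing values and 0 manufacturer control probe sets. The accession in a probe set's ID, without its version, was looked up in a RefSeq gene table of assembly GRCh38.p14, used for names only. This paired 1043 probe sets with 1 symbol, none with several, and left 216 unnamed, 189 of them with IDs of the uc form. A gene with several probe sets (93 of 927 genes) was represented by the one with the highest mean over the 8 arrays.

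Groups and replicate numbers came from the sample titles. Titles of replicates 2 to 4 carry a code that both groups share, taken here to mark the same source of cells, while replicate 1 carries none, so the pairing rests on the labels for 3 of 4 pairs. The correlation of the deviations of same-numbered arrays from their group means, across probe sets, was 0.19, 0.05, 0.02 and -0.13 for replicates 1 to 4. It was 0.02, 0.28 and 0.14 for replicates 1 to 3 without the array labelled resting replicate 4. For differently numbered arrays it ran from -0.302 to 0.261, and from -0.245 to 0.126 without that array. The main fit did not use the pairs, and without that array activated replicate 4 has no partner. The labels do not say that each pair of arrays came from a separate culture, and p-values measure the spread between these samples. The series text lists several stimulation times, but no sample label gives one, and the activated samples were described with 3 days.

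Activated and resting arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided) on the deposited values, with no filter on low signal, and adjusted by Benjamini-Hochberg over all probe sets at a threshold of 0.05. Before the data were examined, 34 gene lists were fixed, with the tests and alternatives. Members of 33 lists were on the array, and 0 of the 15 proliferation genes were. Lists of at least 5 measured genes, 27 in all, were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Camera compares a list with the other genes of the array, here a focused selection, and fry tests a list alone.

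The genes named were chosen by a rule fixed before the data were examined. It took the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, up to 4 members of each list past the threshold, 24 measured genes of sialoglycan synthesis and binding whatever their result (CMAHP, also in the rule, was not analysed here), and the 2 brightest members of each list of other cell types. Because 0 probe sets passed over 8 arrays, the first parts were applied to the fit without the array labelled resting replicate 4, 1 of the planned fits that leave out an array. The rule gave 121 genes, leaving out some items that are not reported here. In a group comparison of 4 against 3 arrays, chance alone separates 5.71% of genes fully, and 468 of 927 genes were separated. Over all 8 arrays as labelled chance separates 2.86%, and 233 genes were separated. The array left out was chosen by its values, so the 468 cannot be set against chance.

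Alternatives fixed beforehand were quantile normalization again, median centring, probe sets above the median level only, the replicate number as a fixed block, for all pairs or those with a code, or as a random effect, a trended and robust variance, array weights, an ordinary test, the mean of a gene's probe sets, and each array left out. Centring on ribosomal protein probe sets, the removal of the close pair of arrays, and the repeat of each alternative on 7 arrays were added after the data were seen. The limma step was tested on simulated data with 200 changed probe sets. At 4 against 4 arrays it recovered 79.3% of changes of 0.5 log2, 90.4% of 1 and 100% of 2, with 0.472% of unchanged probe sets called, and at 4 against 3 it recovered 73.0%, 92.1% and 95.2%, with 0.661% called. With 1 of the 4 resting arrays simulated as activated it recovered 0% at every size. The adjustment depends on how many probe sets change, and 512 had an unadjusted limma p under 0.05 over the 8 real arrays. So this 0% cannot be carried over to the data. Camera recovered a shifted list in 50 of 50 runs and called 6 of 1250 other lists. The simulated probe sets varied independently of each other. The real lists past camera's threshold without the array labelled resting replicate 4 had estimated correlations of 0.0555 to 0.211. So this low rate of calls cannot be carried over to the data either. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.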

Results

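RNA from human peripheral blood B cells was measured on 8 Affymetrix arrays, 4 of resting and 4 of activated cells. Resting cells had been frozen straight after their isolation from the blood of healthy donors by negative selection, which leaves B cells unlabelled and retains the others. Activated cells had been cultured for 3 days with 10 µg/mL of antibodies against IgA, IgG and IgM and 50 nM of a CpG oligonucleotide. The antibodies crosslink the B cell receptor, and the oligonucleotide is a ligand of TLR9. No array was labelled as cells cultured without stimulation, so effects of stimulation and of 3 days of culture cannot be told apart. The table held 1259 probe sets, and 1043 of them were paired with 1 gene symbol each, for 927 genes. The array was a focused one, with enzymes of glycan synthesis and degradation, glycan-binding proteins, cytokines, growth factors and their receptors, so that it sampled a chosen part of the transcriptome. The median log2 signal of an array lay between 6.39 and 6.56, and the number of arrays limits the precision of every value. The study's title puts the question as how glycosylation of B cells is regulated when they are activated.

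The largest rises in activated B cells were those of LGALS3, the chemokine CCL3 and IL2RB, and the largest falls among genes were those of the platelet chemokines PPBP and PF4. LGALS3, a beta-galactoside-binding lectin, had a log2 signal of 12.06 ± 0.21 (SD, n = 4) in activated arrays and 6.90 ± 0.34 (SD, n = 3) in resting replicates 1 to 3, a 35.8-fold rise. IL2RB, a subunit of the interleukin-2 and interleukin-15 receptors, rose 28.1-fold, from 6.49 ± 0.14 (SD, n = 3) to 11.31 ± 0.47 (SD, n = 4). SIGLEC10, an inhibitory lectin that binds sialic acid, fell from 10.00 ± 0.38 (SD, n = 3) to 8.40 ± 0.40 (SD, n = 4). These comparisons leave out the array labelled resting replicate 4, whose values for the same 3 genes were 11.95, 11.31 and 8.77.

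That array lay with the activated ones over the whole table. Across probe sets, which are not independent replicates, its correlation was 0.999 with activated replicate 1, with a standard deviation of the log2 differences of 0.113 and 0 probe sets over 2-fold apart. Its correlation with resting replicates 1 to 3 was 0.970 to 0.972, with 112 to 127 probe sets over 2-fold apart. Resting replicates 1 to 3 differed among themselves in 12 to 25 probe sets at that size, and the activated arrays in 13 to 57. The first principal component held 77.9% of the variance. Resting replicates 1 to 3 scored from -16.3 to -14.9 on it, the activated arrays from 7.72 to 12.5, and the array labelled resting replicate 4 scored 5.17. The close pair of arrays differed less than any other pair, and the 2 were kept as separate samples because the labels put them in different groups. No RNA was labelled as measured on 2 arrays, so whether the pair held the same RNA could not be tested.

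**Figure D1:**
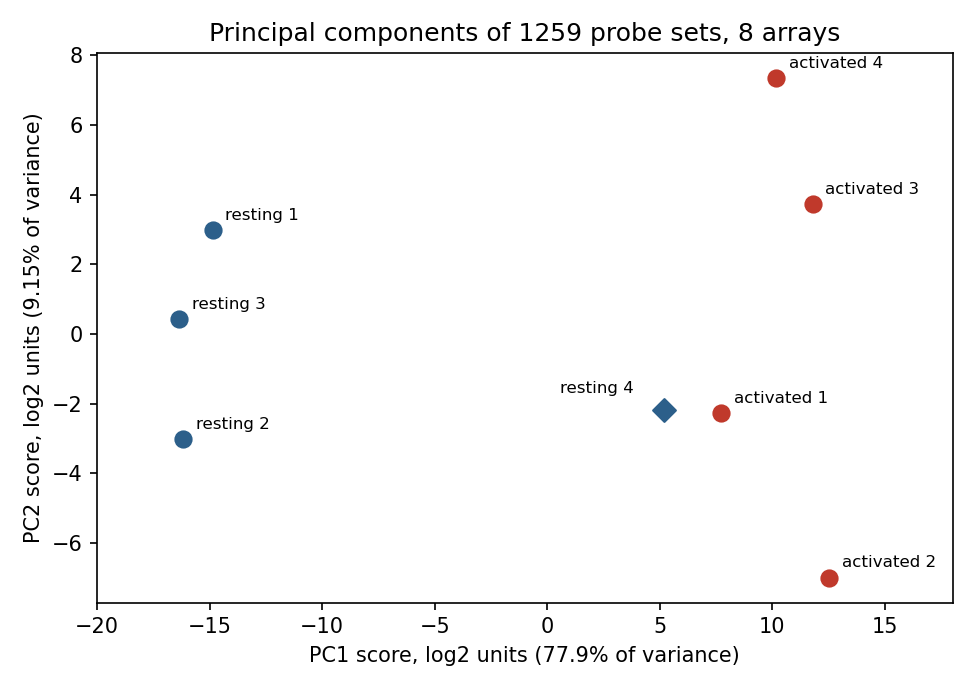
Scores of the 8 arrays on the first (x axis) and second (y axis) principal components of the log2 values, with the share of variance on each axis; red points are activated arrays, blue points resting replicates 1 to 3 and the blue diamond the array labelled resting replicate 4. The diamond sits at 5.17 on the first component, beside activated replicate 1 at 7.72 and away from the other resting arrays at -16.3 to -14.9.

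With all 8 arrays as labelled, 0 of 1259 probe sets passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, while 512 had an unadjusted p under 0.05 against 62.95 expected by chance. The smallest adjusted p, 0.0567, was shared by 132 probe sets, and 448 lay under 0.1. For LGALS3 the log2 fold change over 8 arrays was 3.90 ± 1.14 (SE; limma adjusted p = 0.0583), for IL2RB 3.61 ± 1.10 (limma adjusted p = 0.0606) and for SIGLEC10 -1.29 ± 0.36 (limma adjusted p = 0.0573). An ordinary equal-variance test gave 0 probe sets as well, limma with array weights 547, and limma with a trended and robust variance 201.

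Without the array labelled resting replicate 4, limma called 495 of 1259 probe sets at an adjusted p under 0.05, 192 higher and 303 lower in activated cells. Of these, 147 changed at least 2-fold, 87 higher and 60 lower. In genes, 152 rose and 222 fell. The count of falls depended on the scaling. With each array centred on its median there were 232 higher and 157 lower, with the arrays centred on ribosomal protein probe sets 258 and 132, and after quantile normalization again 191 and 209. With the replicate number as a paired block, 176 were higher and 184 lower. Leaving out resting replicate 3 as well gave 325 calls, 179 of them lower. All 495 kept their direction in each of these fits. Leaving an array out because of its values favours a difference between the groups, and the choice to name genes from this fit was made after the data were seen. The changes given from here on are log2 fold changes of this fit, activated minus resting, with the standard error, over 4 activated and 3 resting arrays. Where other settings moved a list's count by over 1.5 times, its range over 15 of the alternatives that keep all probe sets is given beside it.

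Of 7 measured genes of the sialic acid supply list, which is not limited to its synthesis, 5 rose (range 1 to 5) and 0 fell. Camera gave this list an adjusted p of 0.0174, or adjusted p = 0.502 with an estimated correlation. The count of rises was 1 without resting replicate 2 or 3, and 3 without activated replicate 1 or 3. NANS, the synthase of sialic acid 9-phosphate, rose by 2.24 ± 0.16 (limma adjusted p = 0.000172), from 7.97 ± 0.17 (SD, n = 3) to 10.21 ± 0.26 (SD, n = 4). CMAS, which activates sialic acid as CMP-sialic acid, rose by 0.84 ± 0.19 (limma adjusted p = 0.0145). The call of CMAS was lost without resting replicate 2 or 3. RENBP and SLC17A5 rose too, calls lost in 7 and 3 of 17 alternatives, as did NPL, named after its value was seen. RENBP, SLC17A5 and NPL are members outside synthesis, so the list's count of rises does not measure the synthesis of sialic acid. GNE, the first enzyme of the pathway, was at -0.07 ± 0.11, and SLC35A1, the Golgi CMP-sialic acid transporter, at -0.08 ± 0.17, neither past the threshold (limma adjusted p = 0.666 and 0.735). Of 20 sialyltransferases, 1 rose (range 0 to 3), 4 fell and 15 did not pass. ST3GAL1, which caps core 1 O-glycans with alpha2,3-linked sialic acid, changed by -1.18 ± 0.11 (limma adjusted p = 0.000497). ST3GAL5, the GM3 synthase, changed by -0.81 ± 0.15, and ST3GAL3 by -0.72 ± 0.13. ST6GALNAC4 rose by 0.94 ± 0.27, a call lost in 7 of 17 alternatives. ST6GAL1, which makes the alpha2,6-sialylated ligands of CD22, was high in both groups, at 12.22 ± 0.33 (SD, n = 4) in activated and 11.84 ± 0.19 (SD, n = 3) in resting arrays, and its difference of 0.38 ± 0.19 did not pass (limma adjusted p = 0.152), though it did without activated replicate 2. ST8SIA4, a polysialyltransferase, was at 0.71 ± 0.26 (limma adjusted p = 0.0707), and passed in 6 of 17 alternatives.

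On the removal and recognition of sialic acid, the lysosomal sialidase NEU1 rose by 1.73 ± 0.10 (limma adjusted p = 9.2e-05), and its other probe set by 2.28. CTSA, the protective protein of NEU1, rose by 1.28 ± 0.27. The plasma membrane sialidase NEU3 was below the median level of the array in both groups, with a difference of -0.07 ± 0.06 (limma adjusted p = 0.318). Of 5 genes in the sialidase list, 2 rose and 1, NEU4, fell by 0.22, a call lost in 4 of 17 alternatives. Of 14 Siglecs, the sialic acid-binding lectins of the immunoglobulin family, 0 rose and 4 fell (range 1 to 4, 1 with median centring). SIGLEC10 changed by -1.60 ± 0.26 (limma adjusted p = 0.0041). CD22, the B cell Siglec that restrains receptor signalling, changed by -0.89 ± 0.27 (limma adjusted p = 0.0402), from 12.18 ± 0.29 (SD, n = 3) to 11.29 ± 0.48 (SD, n = 4), a call lost in 9 of 17 alternatives, median centring and the removal of any 1 resting array among them. SIGLEC1 fell by 0.24 and SIGLEC8 fell by 0.19, calls lost in 4 and 11 alternatives. CHST2, a sulfotransferase that adds 6-O-sulfate to N-acetylglucosamine, rose by 1.30 ± 0.24 (limma adjusted p = 0.0063). The carriers of the sulfate donor PAPS, SLC35B3 and SLC35B2, rose by 1.31 and 0.75. Of 16 genes of this sulfation list 3 rose (range 3 to 5) and 5 fell (range 0 to 5). With median centring 4 rose and 0 fell, and with the paired block 3 and 1. Of the falls, CHST10 fell by 0.47, a call lost in 7 of 17 alternatives, and the other 4 by less. CHST4 was below the median level of the array, at 5.12 ± 0.03 (SD, n = 4) and 5.07 ± 0.09 (SD, n = 3), with a difference of 0.05 ± 0.06 (limma adjusted p = 0.455).

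**Figure D2:**
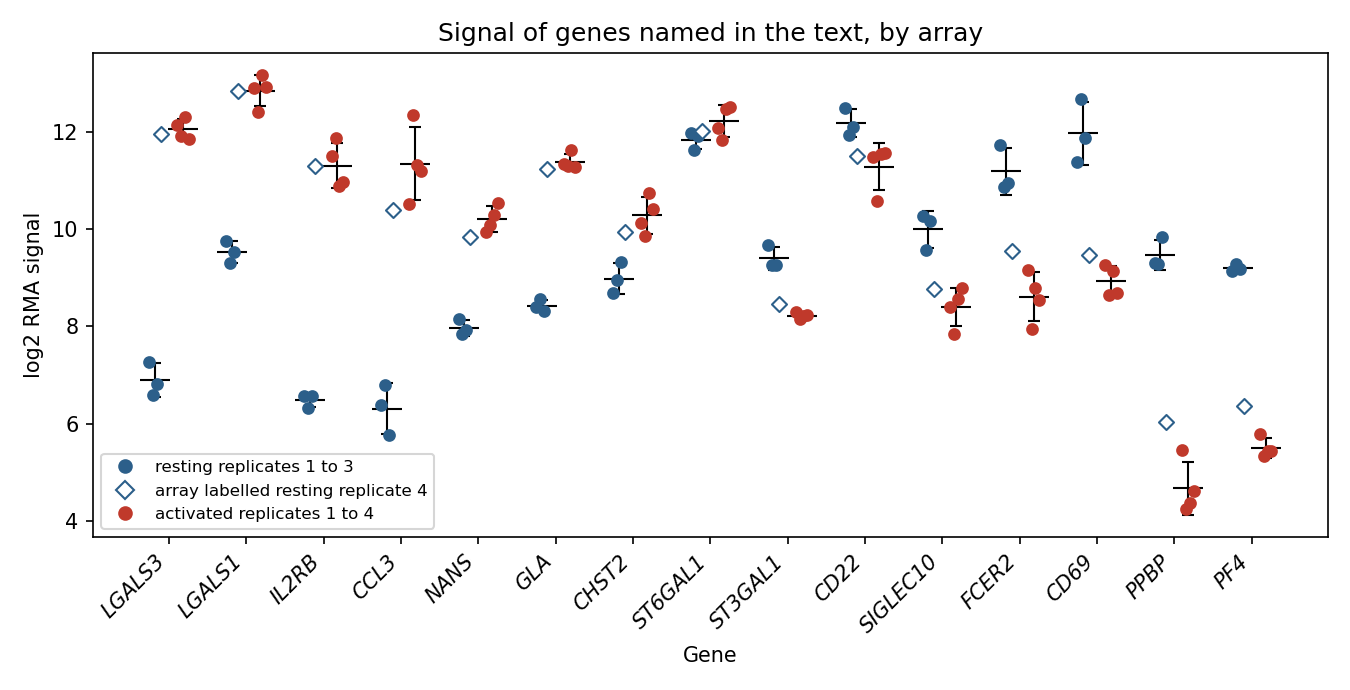
Log2 RMA signal (y axis) of 15 genes (x axis) on each array; blue circles are resting replicates 1 to 3, open diamonds the array labelled resting replicate 4, red circles activated replicates, and black bars the mean and SD of the 3 resting and of the 4 activated arrays. The diamond of LGALS3 lies at 11.95, near the activated mean of 12.06 and far from the resting mean of 6.90, while those of PPBP and PF4 lie at 6.04 and 6.36.

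Of 27 nucleotide sugar synthesis genes 15 rose and 4 fell (range 1 to 4), with a camera adjusted p of 2.4e-05, or adjusted p = 0.368 with an estimated correlation. GFPT1, the entry enzyme of the hexosamine pathway, rose by 1.70 ± 0.09 (limma adjusted p = 8.21e-05), and GMPPB, which makes GDP-mannose, by 1.69 ± 0.13. Of 20 genes of the dolichol-linked precursor and oligosaccharyltransferase list, early steps of N-glycosylation, 11 rose and 3 fell (range 1 to 3), with a camera adjusted p of 0.00187, or adjusted p = 0.368 with an estimated correlation. ALG14 rose by 1.44 ± 0.11 and DAD1, a subunit of the transferase, by 1.35 ± 0.17, while ALG13 changed by -1.32 ± 0.31, a call lost in 2 of 17 alternatives. Of 17 genes of the nucleotide sugar transporter list 8 rose and 2 fell, with SLC35B1 higher by 1.20 ± 0.11. Not all its members carry nucleotide sugars: the PAPS carriers SLC35B2 and SLC35B3, counted in the sulfation list too, are among them. Of 13 genes of N-glycan trimming and branching 7 rose and 3 fell. MAN1A1, a Golgi mannosidase, rose by 2.27 ± 0.28, MGAT2 by 1.78 ± 0.22 and MGAT3, the bisecting enzyme, by 1.39 ± 0.15. MGAT1 rose by 0.61 ± 0.17 (limma adjusted p = 0.0273), a call lost in 7 of 17 alternatives. Of the falls, MAN2A2 kept its call in 17 of 17 alternatives, at -1.47 to -1.07. MGAT5, below the median level of the array, changed by -0.39 ± 0.05, a call lost in 1 of 16 alternatives. FUT8, the core fucosyltransferase, rose by 1.08 ± 0.19, and CANX, the ER lectin calnexin, by 1.72 ± 0.07. In the galactosylation list 4 of 20 rose and 3 fell. B4GALT1 changed by -0.85 ± 0.16, B4GALT3 by 1.27 ± 0.24, B3GNT2, which extends poly-N-acetyllactosamine, by 0.81 ± 0.11, and GCNT2, its branching enzyme, by -0.97 ± 0.13.

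Lysosomal enzymes of glycan degradation moved both ways, with 13 of 29 higher and 6 lower (camera adjusted p = 0.00997, or adjusted p = 0.723 with an estimated correlation). GLA, alpha-galactosidase A, rose 7.78-fold, from 8.43 ± 0.12 (SD, n = 3) to 11.39 ± 0.16 (SD, n = 4). GM2A, the GM2 activator protein, rose by 1.62 ± 0.22. Set against the other genes of this focused array, camera with a preset correlation of 0.01 put 5 of 27 lists past an adjusted p of 0.05 without the array labelled resting replicate 4. They were nucleotide sugar synthesis, the dolichol list, lysosomal degradation and sialic acid supply, all upward, and platelet markers, downward. NANS, CMAS and GNE belong to both nucleotide sugar synthesis and sialic acid supply, so the results of these lists are not separate. With an estimated correlation 0 lists passed. With the replicate block the adjusted p of lysosomal degradation was 0.0747, and without resting replicate 2 that of sialic acid supply was 0.0524. Over all 8 arrays the same 5 lists passed with the preset correlation, together with the nucleotide sugar transporters (limma camera adjusted p = 0.0385), and 0 passed with an estimated correlation, at adjusted p = 0.547 for each of the upward ones and 0.680 for platelet markers.

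**Figure D3:**
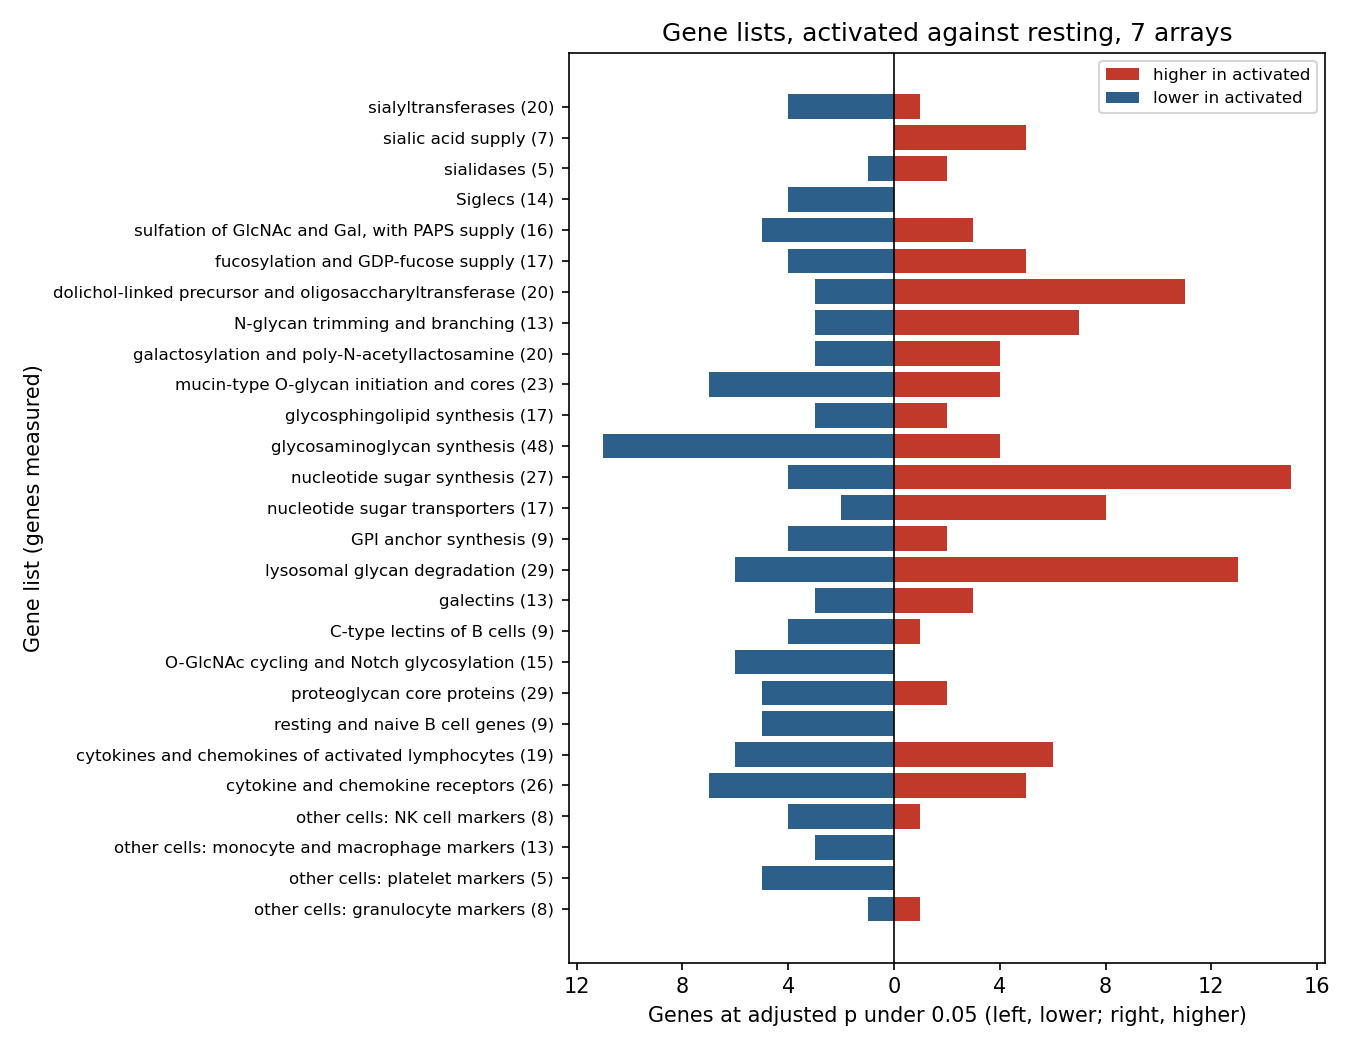
Genes past an adjusted p of 0.05 in limma without the array labelled resting replicate 4 (x axis, number of genes), higher (red, to the right) or lower (blue, to the left) in activated cells, for each list with at least 5 measured genes (y axis, number measured in brackets). Nucleotide sugar synthesis has 15 of 27 genes to the right, and glycosaminoglycan synthesis 11 of 48 to the left, a number that was 5 with median centring.

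In mucin-type O-glycan synthesis 4 of 23 genes rose and 7 fell (range 1 to 7). GALNT2 and GALNT1, which start O-glycans, rose by 1.96 ± 0.20 and 1.11 ± 0.11, and GALNT3 changed by -1.11 ± 0.15. C1GALT1, the core 1 synthase, was at 0.46 ± 0.22 and the core 2 enzyme GCNT1 at -0.62 ± 0.62, neither past the threshold (limma adjusted p = 0.132 and 0.439), though C1GALT1 passed in 2 of 17 alternatives. In glycosaminoglycan synthesis 4 of 48 rose (range 4 to 7) and 11 fell (range 4 to 11). With median centring 6 rose and 5 fell, with the paired block 4 and 5, and without resting replicate 3 as well 4 and 4. CSGALNACT1, which starts chondroitin chains, changed by -2.25 ± 0.66 (limma adjusted p = 0.0347), a call lost in 6 of 17 alternatives, and CHST7 rose by 1.22 ± 0.13. Of 29 proteoglycan core proteins 2 rose (range 2 to 5) and 5 fell (range 1 to 6), with SRGN, serglycin, higher by 1.78 ± 0.20 and SPOCK2 at -1.67 ± 0.34. In O-GlcNAc cycling and Notch glycosylation 0 of 15 rose (range 0 to 1) and 6 fell (range 3 to 6). NOTCH2 fell by 1.40, and OGA, the O-GlcNAc hydrolase, fell by 1.20. In fucosylation 5 of 17 rose and 4 fell (range 1 to 5), in glycosphingolipid synthesis 2 of 17 rose and 3 fell (range 1 to 3), and in GPI anchor synthesis 2 of 9 rose (range 1 to 2) and 4 fell, where PIGH fell by 1.23. Of 3 measured ER folding genes only CANX passed (range 1 to 2). Of 13 galectins 3 rose and 3 fell. LGALS1 rose 10-fold, from 9.53 ± 0.23 (SD, n = 3) to 12.85 ± 0.32 (SD, n = 4). LGALSL rose by 0.88 ± 0.19, a call lost in 1 of 17 alternatives, and LGALS9 changed by -0.98 ± 0.16 (limma adjusted p = 0.00395).

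Of 9 measured genes of resting and naive B cells 5 fell, 0 rose and 4 did not pass. As a list they did not pass camera (adjusted p = 0.143, or adjusted p = 0.742 with an estimated correlation). FCER2, the low-affinity IgE receptor CD23, went from 11.19 ± 0.48 (SD, n = 3) to 8.61 ± 0.51 (SD, n = 4), a change of -2.58 ± 0.33 (limma adjusted p = 0.00163). CXCR4 and CXCR5, chemokine receptors of B cell homing, changed by -1.79 ± 0.24 and -0.93 ± 0.18, and IL4R by -1.76 ± 0.32. Of 4 measured activation markers, IL2RA and ICAM1 rose by 1.03 ± 0.33 and 0.60 ± 0.09, and CD69 fell by 3.04 (limma adjusted p = 0.000712). The calls of IL2RA and ICAM1 were lost in 6 and 1 of 17 alternatives, and in other settings 1 to 2 of these markers rose and 1 to 2 fell. JUNB, an immediate early transcription factor, changed by -2.87 ± 0.30. Of 9 C-type lectins 1 rose (range 0 to 2) and 4 fell, where CLEC4A fell by 1.90 and CLEC2B fell by 1.71. Of 19 cytokines and chemokines 6 rose and 6 fell (range 3 to 7). CCL3, CCL4 and CCL22 rose 32.8-fold, 25.9-fold and 12.5-fold, and CCL3 and CCL4 have near-identical gene copies that their probe sets may also measure. VEGFA rose by 1.82 ± 0.40, a call lost in 1 of 17 alternatives. Of 26 cytokine and chemokine receptors 5 rose and 7 fell, with IL12RB2 higher by 1.52 ± 0.21. Of 2 measured plasma cell genes, CCR10 rose by 0.98 ± 0.16 and 0 fell (range 0 to 1). Of the remaining genes with the largest changes, the cell cycle kinase subunits CKS2 and CKS1B rose by 3.13 ± 0.45 and 2.21 ± 0.30 and the adhesion protein CD58 by 2.41 ± 0.21, while HES1, a Notch target, changed by -2.37 ± 0.61, IGF1R by -1.75 ± 0.19 and PECAM1 by -1.75 ± 0.31. The call of HES1 was lost in 4 of 17 alternatives.

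Of the 4 lists of other blood cells with enough genes to test, platelet markers alone passed camera, with an adjusted p of 0.00461, or adjusted p = 0.368 with an estimated correlation. All 5 measured platelet markers were lower in activated arrays (range 3 to 5, 3 with median centring). PPBP and PF4, platelet chemokines, went from 9.47 ± 0.31 (SD, n = 3) to 4.67 ± 0.54 (SD, n = 4) and from 9.20 ± 0.07 (SD, n = 3) to 5.50 ± 0.20 (SD, n = 4), and SELP, P-selectin, changed by -0.78 ± 0.09. Of 8 NK cell markers 1, KLRG1, rose by 0.96 ± 0.11, and 4 fell (range 1 to 5), or 1 after quantile normalization, median centring or the paired block. Among the falls KLRF1 kept its call in 16 of 16 alternatives, at -1.31 to -0.872. Of 13 monocyte and macrophage markers 0 rose and 3 fell (range 0 to 4), and of 8 granulocyte markers HPSE rose by 1.34 ± 0.19 and SIGLEC8 fell (range 0 to 1). The T cell marker CD2, the plasmacytoid dendritic cell markers IL3RA and CLEC4C and the erythroid gene EPOR did not pass, though CD2 did in 3 of 16 alternatives. Adjusted over the list alone, the counts were those given over all probe sets, except for 3 Siglecs lower, 4 sulfation genes higher, 9 glycosaminoglycan genes lower, 16 nucleotide sugar synthesis genes and 9 transporters higher, 5 GPI anchor genes lower, 7 cytokines lower, 6 receptors higher, 5 NK cell and 2 monocyte markers lower and CD2 lower. Over all 8 arrays no list member passed over all probe sets, and adjusted over the list alone 0 of 14 Siglecs, 48 glycosaminoglycan genes, 29 proteoglycan core proteins, 17 glycosphingolipid genes, 13 monocyte markers and 8 granulocyte markers did, nor did any T cell, plasmacytoid dendritic cell or erythroid marker. Of the other lists, 15 of 29 lysosomal, 14 of 20 dolichol, 11 of 27 nucleotide sugar synthesis, 9 of 17 transporter, 9 of 13 trimming, 8 of 16 sulfation, 6 of 23 mucin-type, 5 of 20 galactosylation, 5 of 9 GPI anchor, 4 of 17 fucosylation, 4 of 15 O-GlcNAc and Notch, 3 of 5 sialidase, 2 of 7 sialic acid supply, 2 of 20 sialyltransferase and 1 of 3 ER folding genes passed in that way. So did 11 of 26 receptors, 8 of 19 cytokines, 5 of 13 galectins, 5 of 5 platelet markers, 4 of 9 C-type lectins, 4 of 9 resting B cell genes, 2 of 8 NK cell markers, 2 of 4 activation markers and 1 of 2 plasma cell genes.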

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

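The tests on the array labelled resting replicate 4 were chosen after its position was seen, and those on platelet genes and on the excess of falls before their results were seen. The counts over all probe sets, the repeats of the sign test, and the choice to leave median centring out of the test on scaling were also made after the data were seen. In 32 of 244 sets of 4 arrays, 1 array lay far from the other 3 by the ratio of its gap to the range, where chance gives about 1 in 20, or 12.2, for values that were not chosen. Of these, 21 were at the array labelled resting replicate 4, but most of the genes were named from the fit that leaves this array out, so that count cannot be set against chance. Over all probe sets, which were not chosen but are not independent, 113 of 1259 resting sets stood out in this way, 77 of them at that array, and 59 of 1259 activated sets, against 62.95 by chance in each. The ratio was 0.931 for its first principal component. Among higher values it was 0.87 for LGALS1, 0.873 for LGALS3, 0.949 for IL2RB, 0.879 for CCL22, 0.918 for GLA, 0.839 for NANS, 0.831 for B3GNT2, 0.854 for CANX, 0.885 for MGAT3, 0.864 for GFPT1, 0.948 for GMPPB, 0.931 for TGFBR3, 0.905 for CCR10 and 0.928 for HPSE. Among lower values it was 0.84 for MGAT5, 0.894 for LGALS9, 0.855 for PPBP, 0.951 for PF4, 0.844 for SPOCK2 and 0.879 for SELP. In the activated group, replicate 1 stood apart for NEU1 (0.92), HES1 (0.931), CXCR4 (0.939), SIGLEC1 (0.918), SLC35C1 (0.844) and CANX (0.854), replicate 2 for CD22 (0.918), PECAM1 (0.94), GALNT3 (0.937) and PIGH (0.848), and replicate 4 for CMAS (0.88).

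The array labelled resting replicate 4 lay with the activated arrays. A swap with an activated array is argued against, since the lowest position of the 4 activated arrays, on a line from resting (0) to activated (1), was 0.844. An activated sample under a resting label stays open, since this array's position was 0.793, within 1 SD (0.0971) of that, though against activated replicates 2 to 4 alone it was 0.751, lower by 0.0925 and so only just within it. A mixture of resting and activated RNA also stays open, since the array had gone further along for rises than for falls, by 0.0723 of the change (0.0549 against activated replicates 2 to 4 alone), against 0.0164 at most in an activated array, a margin that is small beside the range of the 4 activated arrays, whose lowest value was -0.134. The same RNA as activated replicate 1 under 2 labels (correlation 0.999), a resting sample that was activated before freezing, or cells taken at another time, may give the same values and was not tested. The title of this array shares a code with activated replicate 4. Of the activated arrays that was the least like it, at a correlation of 0.991, with 30 probe sets over 2-fold apart. Activated replicate 1, the closest, carries no code.

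PPBP and PF4 fell the most of the named genes. Fewer platelets may account for this, but the test cannot decide it: the other 3 measured platelet markers all fell, with a median log2 change of -0.308, yet all 3 lay below the median level of the array. A loss of all cells other than B cells also stays open. The median change over 6 brighter markers was -0.239, 6 of 6 below 0 (exact sign test, 2-sided, p = 0.0312, n = 6). In 4 of 17 alternatives 1 marker lay above 0 and p was 0.219. Markers read on the same arrays are not independent, and the median change of all probe sets was -0.0859, so the test cannot decide this. With median centring 6 of 6 stayed below 0. The change of the 6 markers is small beside those of PPBP (-4.81) and PF4 (-3.70). Their means in resting replicates 1 to 3 were 6.74 to 7.38, near the median level of 6.52 there, which limits how far they could fall. Among markers below the median level, KLRG1 and HPSE rose, while the NK cell marker KLRF1 fell, at -1.31 to -0.872 over 16 alternatives, past the threshold in each. Of the 6 markers 2 passed the threshold, KLRD1 and SIGLEC1, calls lost in 6 and 4 of 17 alternatives. Another probe set of KLRD1 was at limma adjusted p = 0.617. Another probe set of CSF3R, also among the 6, changed by -0.285 (limma adjusted p = 0.0134). A change within B cells was not tested.

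More probe sets fell than rose without the array labelled resting replicate 4, 303 against 192. Whether a shift left by the scaling carries the excess cannot be told apart from a wider fall, since quantile normalization again left 52.2% of calls as falls (exact 95% interval 47.2% to 57.2%, from 61.2%), and median centring, at 40.4%, moves that share by construction. With ribosomal centring, which takes these genes as unchanged, the share was 33.8%. Whether dim probe sets carry the excess cannot be told apart from a general excess, since the share was 53.7% above the median level (exact 95% interval 48.2% to 59.2%) and 76.9% below it. These intervals take probe sets as independent, which they are not, and do not measure the spread between arrays. A wider fall in activated cells was not tested. The median of every activated array (6.39 to 6.45) lay below that of every resting one (6.47 to 6.56), which a wider fall and a shift left by the scaling would both give.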

How the results depend on the processing

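The removal of the close pair of arrays, ribosomal centring and all alternatives on 7 arrays were chosen after the data were seen, as were the counts of splits over 8 arrays. Over 8 arrays the 0 calls, 0 calls at 2-fold and 0 list members became 185, 79 and 98 with probe sets above the median level only (fewer tested), 201, 74 and 88 with a trended robust variance, 547, 137 and 213 with array weights (0.273 for resting replicate 4), and 398, 146 and 167 without the close pair. Leaving out 1 array gave 0 to 495 calls, 0 to 147 at 2-fold and 0 to 201 list members, above 0 only without resting replicate 4. Every other alternative run, the paired replicate block included, gave 0. The 6 lists past camera's threshold became 0 with an estimated correlation, 0 with fry and 2 above the median level, and 4 to 7 without 1 array. On 7 arrays the 303 falls became 157 with median centring, 171 above the median level, 132 with ribosomal centring, 184 with the paired replicate block and 138 with that block for the pairs with a code, where the calls were 310. The block kept 335 of the 495 calls. Leaving out 1 more array gave 325 to 454 calls and 179 to 267 falls, the lowest without resting replicate 3. The 5 lists became 0 with an estimated correlation, 20 with fry and 1 above the median level. The cause was not tested unless given. Ribosomal centring moved the median change from -0.09 to 0.05. Over 8 arrays the count of splits decides nothing, since all 35 must give at least the real 0 (highest other 0). By unadjusted p under 0.05, 1 of the 35 gave 512 (highest other 406, with an activated array in place of resting replicate 4), and 1 of 35 splits of the 7 arrays gave 495 calls (highest other 0), so chance can be excluded only if arrays are exchanged freely, and apart from the choice of array. The splits that part every replicate pair, 8 in each case (highest other 406 and 0), are too few for a share under 0.05.

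Of the alternatives for named genes over 8 arrays, 1945 kept direction and side, 436 passed the threshold newly and 20 reversed, all of genes far from the threshold. NEU3 was at 0.00717 after quantile normalization, 0.0252 with median and 0.0488 with ribosomal centring. SLC35A1 was at 0.0217 and 0.0452 with these centrings and 0.0520 with the paired replicate block of coded pairs. GNE was at 0.0155 and 0.0391 with the centrings, and CLEC4C at 0.0102 with the ribosomal one. SIGLEC5 was at 0.00741 and 0.0310 with the centrings and 0.184 with array weights. With 1 array left out, CHST4 ran from -0.00142 (without resting replicate 1) to 0.0551, GCNT1 from -0.788 to 0.0590 (without resting replicate 1), SLC35A1 from -0.175 to 0.0793 (without resting replicate 1), SIGLEC5 from -0.220 to 0.0877 (above 0 without resting replicate 1 or 4 or activated replicate 4), and IL3RA from -0.419 to 0.145 (above 0 without resting replicate 3 or activated replicate 2). On 7 arrays the block of coded pairs alone ended the calls of MGAT5, LGALSL, ICAM1 and VEGFA. Centring on manufacturer controls was not run, as none were in the table. Low signal limits what can be seen, since no detection calls were used.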

Other observations

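The gene families here were chosen after the data were seen, and their counts come from the fit without the array labelled resting replicate 4. Of 4 measured proteasome subunits 3 were higher in activated cells and 0 lower, also after quantile normalization, median centring and ribosomal centring. PSMB2 rose by 2.00 ± 0.18, from 9.33 ± 0.17 (SD, n = 3) to 11.33 ± 0.32 (SD, n = 4) (limma adjusted p = 0.000442), and PSMB3 by 1.09 ± 0.19. Of 12 receptors of the TGF-beta family 3 rose and 5 fell, with the same counts under each of the 3 scalings. BMPR2 changed by -1.34 ± 0.12 and TGFBR2 by -0.77 ± 0.12, while TGFBR3 and ACVR1 rose by 1.51 ± 0.34 and 0.69 ± 0.15. Of 34 CC and CXC chemokines 3 rose and 7 fell, with CCL5 at -1.30 ± 0.20. This balance depended on the scaling: 6 rose and 2 fell after quantile normalization and with median centring, and 7 and 2 with ribosomal centring. Of 41 ribosomal proteins 1 rose and 14 fell, while 4 fell with median centring and 5 after quantile normalization. With ribosomal centring 3 fell, but that setting moves this family by construction and is no check on it. Of 11 mucins none passed.

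AREG, an epidermal growth factor receptor ligand outside the rule for named genes, was higher in resting arrays with CD69 and JUNB, at 8.35 ± 1.53 (SD, n = 3) against 5.76 ± 0.81 (SD, n = 4) (limma adjusted p = 0.0345). Of the 216 probe sets without a gene symbol 24 rose and 52 fell. The largest rises were those of uc001egp.1_psr1_a_at, by 2.33 ± 0.19, and uc002wbb.1_psr1_at, by 2.02 ± 0.14. The largest falls, -3.77 ± 0.56 and -3.53 ± 0.49, were those of uc001ykw.1_psr1_at and uc001ykw.1_psr1_x_at, which share an ID root.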
